A study of Homo sapiens with 8 samples.

How the data were processed

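RNA was sequenced from H9 cells, an established human embryonic stem cell line, grown on gels of 2 stiffnesses, 400 Pa (soft) and 60 kPa (stiff). Cells were taken undifferentiated (day 0) or after induction with a cocktail of bFGF, Activin, VEGF and BMP4 (day 3.5). Per the labels, total RNA was recovered with TRIzol, and 8 libraries fall into 4 groups of 2. The labels do not say whether the 2 libraries of a group came from separate cultures. Any p-value of the authors' comparison therefore measures only the spread between these libraries, which may be technical. The Fisher exact tests given below count genes and do not measure that spread.

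The deposited files hold 1 table per day. Each gives, per gene locus, 1 FPKM for the 400 Pa group and 1 for the 60 kPa group, made by the authors with Cufflinks on build hg19, per the submitters' processing notes. The versions, aligner and gene annotation are not given in the sources used here. The deposited tables also hold a log2 ratio of 60 kPa over 400 Pa, a test statistic (a score of the authors' comparison), a p-value and a q-value. No value per library was analysed here. Read depth is therefore unknown, and no SD or count of replicates stands behind any single value. Recomputing a Benjamini-Hochberg adjustment over the loci the authors tested returned the deposited q-values. The smallest deposited p-value was 5e-05 on both days, which the authors' procedure does not go below.

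The design fixed before the data were examined foresaw a test over libraries if such values were given, and the authors' own comparison otherwise. The calls are therefore those of the authors' deposited tables at q below 0.05, counted over loci with an FPKM of at least 1 in 1 of the groups and once per gene symbol. Changes are log2((FPKM + 1) on 400 Pa / (FPKM + 1) on 60 kPa), so that a positive value is higher on the soft gel; the pseudocount of 1 understates the change of low genes. The standard error (SE) given beside a change is the deposited log2 ratio divided by the deposited test statistic. It is an approximation and lies on the scale of the ratio without pseudocount. The 2 tables were made separately, so each test was run within a day, and levels of different days are only set side by side.

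A total of 29 gene lists with 581 distinct genes were fixed before the data were examined. For each list the share of called genes was compared with that of the other tested genes by a two-sided Fisher exact test, with Benjamini-Hochberg adjustment over the lists of a day. The median change of a list was set against 10000 random lists of the same size matched on mean FPKM in 20 bins. Genes in a list are not independent, so these tests describe the lists in these libraries. The list of mitochondrially encoded genes had no measured member on either day. The difference between days was computed from both deposited log2 ratios and their implied errors (normal approximation), adjusted over the loci compared.

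Named genes followed a rule also fixed in advance. It took, per day, the 8 called genes with the largest change in each direction with an FPKM of at least 5 in a group. It added up to 4 called members of each list, or up to 2 highly expressed members where none was called, and 12 genes named whatever their result. Unnamed loci were counted and not named, and some genes that the rule takes are not reported here. Coordinates are those of the authors' tables on hg19, written 1-based. The GENCODE release 29 annotation was used only for gene symbols and to find which genes hold a small RNA gene. It matched 82.9% of the symbols looked up on each day, and none of its coordinates are printed. Loci where the authors' tables merge several genes, 1325 at day 0 and 1358 at day 3.5, cannot be split between their genes. The strand setting of the authors' counting is not given, so antisense and overlapping genes cannot be told apart.

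The steps were tested on simulated data. With 20-gene lists and no shift, 5.0% (day 0, 14559 genes) and 7.0% (day 3.5, 15330 genes) of 100 simulated lists lay outside the 95% range, and all lists shifted by 0.5 did. The difference between days, simulated over 17043 loci with the implied errors, recovered 5.0% of 100 genes that differed by 2 and 46.0% of 100 that differed by 4 on the log2 scale. It therefore detects only large differences. The list simulation shuffled the changes over genes and drew members at random, so it does not cover the correlated members of real lists. The simulation of days drew its noise from the same implied errors that it tested with, so it does not check those errors. Alternatives were other pseudocounts (0.1 and 0.5), other FPKM minimums, other thresholds, a minimum fold of 2, a new adjustment, centring on the median gene and counting every row. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.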

Results

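The transcriptome of H9 human embryonic stem cells was compared between a soft (400 Pa) and a stiff (60 kPa) substrate, before induction (day 0) and after 3.5 days of mesoderm induction. There were 4 groups of 2 libraries, and the authors' value for each gene is 1 FPKM per group. The depth of the libraries is unknown. The tables list 33575 gene loci at day 0 and 34690 at day 3.5. Of these, 17315 and 18228 were tested by the authors and reached the FPKM minimum. The 10 loci with the highest FPKM held between 44.9% and 52.1% of the summed FPKM of a group.

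Levels of lineage genes were first set side by side across the days, without a test, because the tables were made separately. POU5F1, a core pluripotency factor, was at 339.8 FPKM on 400 Pa and 409 on 60 kPa at day 0, and at 114 and 122 at day 3.5. NANOG went from 16.7 and 24.9 FPKM to 2.46 and 3.16. The primitive streak gene MIXL1 was at 0.0907 FPKM on 400 Pa and 0.376 on 60 kPa at day 0, and at 7.60 and 6.39 at day 3.5. The median pluripotency-list gene was lower at day 3.5 by 1.72 log2 units on 400 Pa (18 genes, median -1.72) and by 1.17 on 60 kPa (median -1.17). The median mesoderm-list gene was higher by 3.03 on 400 Pa (23 genes) and by 2.41 on 60 kPa (18 genes); over the 18 genes common to both it was 3.31 and 2.41. With a pseudocount of 0.1 in place of 1 the first pair of values became 4.89 and 4.29.

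**Figure D1:**
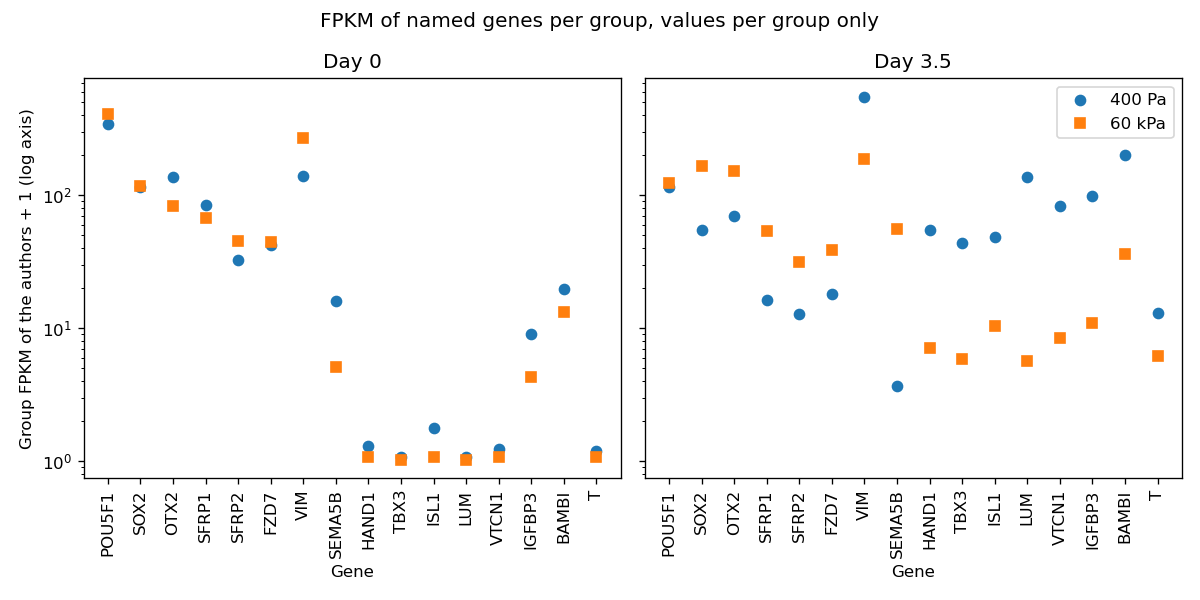
Group FPKM plus 1 (log axis) of 16 genes on 400 Pa (circles) and 60 kPa (squares) at day 0 (left) and day 3.5 (right). Each point is the authors' value of a group of 2 libraries, without error bars, since no values per library were used. At day 3.5, LUM stands at 136 FPKM on 400 Pa and 4.69 on 60 kPa.

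The main comparison asked which genes depended on stiffness in the induced cells. At day 3.5, the called members of the mesoderm, amnion and trophoblast and BMP target lists, 13 of 25, 8 of 15 and 8 of 18 in the authors' deposited table, were all higher on the soft gel. The called members of the neuroectoderm list (3 of 11) and the WNT antagonist list (3 of 9) in the authors' deposited table were all higher on the stiff gel. The authors' deposited table called 243 loci at q below 0.05, with 197 higher on 400 Pa and 46 higher on 60 kPa. The median SE of the called loci was 0.80 log2 units. At an unadjusted p below 0.05 the authors' deposited table held 1080 of the 18228 tested loci. That share is slightly above the 0.05 that uniform p-values without any difference would give. Of the called loci, 16 were listed at 0 in a group, 17 were unnamed and 9 merged several genes. Of the 227 called loci with a finite statistic, 36 had a test statistic in the authors' deposited table too small to pass a two-sided normal test at 0.05, so their calls and their implied errors do not go together.

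Mesoderm genes formed the list with the highest share of calls after amnion and trophoblast genes. In the authors' deposited table, 13 of 25 tested members were higher on 400 Pa and none on 60 kPa (16 and 0 when adjusted over the list alone; Fisher exact test, adjusted p = 1.07e-16). The median change was 1.66, against -0.13 to 0.21 for 95% of matched lists. HAND1, a transcription factor of lateral and extraembryonic mesoderm, was at 53.8 FPKM on 400 Pa and 6.07 on 60 kPa (change 2.95, SE 0.59). TBX3 was at 42.4 and 4.90 (2.88, SE 0.90), MEIS1 at 62.4 and 7.75 (2.86, SE 1.19) and ISL1 at 47.7 and 9.44 (2.22, SE 0.53). T, the brachyury gene of early mesoderm, was at 12.0 and 5.15 FPKM, with q = 0.594 in the authors' deposited table. MIXL1, EOMES and KDR were not called either in the authors' deposited table. KDR, a VEGF receptor, was at 23.0 and 14.8 FPKM (change 0.61, SE 0.46).

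Among amnion and trophoblast genes, 8 of 15 tested members were called higher on 400 Pa and none on 60 kPa in the authors' deposited table (11 and 0 when adjusted over the list alone; adjusted p = 1.4e-10). VTCN1 was at 81.3 FPKM on 400 Pa and 7.44 on 60 kPa (change 3.28, SE 0.53), and IGFBP3 at 98.2 and 9.94 (3.18, SE 0.58). CDX2, a caudal and trophectoderm factor, was at 14.8 and 1.74 (2.53, SE 1.08). Of the BMP targets, 8 of 18 were called higher on 400 Pa and none on 60 kPa in the authors' deposited table (12 and 1 when adjusted over the list alone; adjusted p = 6.11e-10). They include BAMBI, a BMP-induced pseudoreceptor, at 199 and 35.2 FPKM (2.47, SE 0.47), and share HAND1, TBX3 and CDX2 with the lists above. Of the WNT targets, 5 were called higher on 400 Pa and 1 on 60 kPa among 20 in the authors' deposited table (7 and 1 when adjusted over the list alone; adjusted p = 1.97e-06). LEF1, a transcription factor of WNT signalling, was at 33.0 and 7.45 (2.01, SE 0.77). Among these calls, BAMBI and CDX2 are also BMP targets. FZD7, the call on the stiff side, is also on the list of WNT ligands and receptors. The results of these lists are therefore not separate.

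The called members of the mesenchymal, matrix, fibroblast and HOX lists were also all higher on the soft gel in the authors' deposited table. Of 14 mesenchymal transition genes, 5 were called higher on 400 Pa and none on 60 kPa in the authors' deposited table (8 and 0 when adjusted over the list alone; adjusted p = 6.12e-06). SNAI2 was at 28.2 and 2.85 FPKM (2.92, SE 0.63) and CDH11 at 106 and 33.6 (1.62, SE 0.79). PRRX1 was at 16.4 and 0.726, with a change of 3.33 and an SE of 2.42. Of 35 matrix genes, 6 were called higher on 400 Pa and none on 60 kPa in the authors' deposited table (7 and 0 when adjusted over the list alone; adjusted p = 4.58e-05). COL6A3 was at 16.2 and 1.08 FPKM (3.04, SE 1.12) and COL2A1 at 41.5 and 9.18 (2.06, SE 0.77). Of 11 fibroblast markers, LUM, COL3A1 and DCN were called higher on 400 Pa and none on 60 kPa in the authors' deposited table (5 and 0 when adjusted over the list alone; adjusted p = 0.00127). LUM was at 136 and 4.69 FPKM (4.59, SE 0.81), DCN at 38.7 and 3.79 (3.05, SE 1.38). COL1A2 (18.2 and 24.2 FPKM) and THY1 (25.5 and 26.8), chosen after their values were seen, were not called in the authors' deposited table. Of 10 HOX genes, HOXA13 and HOXB1 were called higher on 400 Pa in the authors' deposited table (adjusted p = 0.0203; 4 and 0 when adjusted over the list alone), and all 10 lay above 0.

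The called neuroectoderm genes lay on the stiff side. In the authors' deposited table, 3 of 11 were called higher on 60 kPa and none on 400 Pa (4 and 0 when adjusted over the list alone; adjusted p = 0.00127). OTX2, a forebrain and epiblast transcription factor, was at 69.3 FPKM on 400 Pa and 152 on 60 kPa (change -1.12, SE 0.48). Outside that list, HESX1, a factor of the anterior neural plate, was at 5.11 and 45.3 (-2.92, SE 0.70), FEZF1 at 15.8 and 99.4 (-2.58, SE 0.87) and LHX5 at 4.12 and 20.6 (-2.07, SE 0.68). Of 9 WNT antagonists, SFRP1, SFRP2 and FRZB were called higher on 60 kPa and none on 400 Pa in the authors' deposited table (adjusted p = 0.000825; 3 and 0 when adjusted over the list alone). SFRP1 was at 15.4 and 52.5 FPKM (-1.70, SE 0.53), SFRP2 at 11.7 and 30.5 (-1.31, SE 0.49) and FRZB at 1.84 and 9.71 (-1.92, SE 0.67). The median of the antagonist list was -0.14 and lay within 95% of matched lists, and 3 of its 9 members lay above 0. Among WNT ligands and receptors, 2 were called in each direction of 28 in the authors' deposited table (10 higher on 400 Pa and 3 on 60 kPa when adjusted over the list alone; adjusted p = 0.00169). WNT8A (26.1 and 9.10 FPKM) and WNT5A (24.8 and 8.03) were higher on 400 Pa; FZD5 (18.3 and 76.9) and FZD7 (17.2 and 37.9) were higher on 60 kPa.

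Of 18 pluripotency genes, PRDM14 and SFRP2 were called higher on 60 kPa and none on 400 Pa in the authors' deposited table, and the share missed the threshold (adjusted p = 0.0548; 3 and 0 when adjusted over the list alone). Of the 18, 17 lay below 0, and the median of -0.51 lay below 95% of matched lists (-0.11 to 0.23). SOX2 was at 54.0 and 164 FPKM with q = 0.519 in the authors' deposited table. POU5F1 and NANOG were not called in the authors' deposited table. The primitive streak list, as fixed in advance, had 3 calls higher on 400 Pa and 1 on 60 kPa of 15 in the authors' deposited table (Fisher exact test, adjusted p = 0.000206). Adjusted over the list alone these were 4 and 1. Calls on the soft side include GATA6 (6.76 and 1.58 FPKM) and CDX1 (6.23 and 1.27). The only call on the stiff side was LHX5, already given above beside HESX1 and FEZF1, so it is no separate result. Of the 15 members, 13 lay above 0. Haemato-endothelial genes had 1 call in each direction of 11 in the authors' deposited table (adjusted p = 0.0227; 3 and 1 when adjusted over the list alone). FLI1 was at 2.31 and 0.367 FPKM, and VWF at 0.873 and 6.12. VWF, the call on the stiff side, had a change of -1.93 with an SE of 1.58 and a statistic of 1.78 in the authors' deposited table. It holds a small RNA gene, as do SFRP1, COL3A1 and GATA6 among the called genes named above for this day.

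The other lists did not pass the test at day 3.5. YAP and TAZ targets had 1 call (IGFBP3) of 20 in the authors' deposited table (adjusted p = 0.394), and 6 higher on 400 Pa and 1 on 60 kPa when adjusted over the list alone. Of the 20, 14 lay above 0, and the median of 0.34 lay above 95% of matched lists (-0.17 to 0.22). CTGF was at 1.83 FPKM on 400 Pa and 3.58 on 60 kPa without a call in the authors' deposited table. Serum response factor and actin genes had 2 calls higher on 400 Pa of 24 in the authors' deposited table (adjusted p = 0.0872). ACTC1 was at 88.3 and 8.60 FPKM and TPM1 at 780.4 and 243. No focal adhesion, epithelial, cell cycle, p53, glycolysis, stress, cholesterol, histone, ribosomal protein or FGF-ERK list gene was called in the authors' deposited table. Of these lists, the medians of focal adhesion (0.38, 20 of 22 above 0), FGF-ERK (0.41, 9 of 13) and histone genes (0.33, 13 of 14) lay above 95% of matched lists. Those of cell cycle (-0.10, 16 of 24 below 0) and cholesterol genes (-0.19, 8 of 13) lay below. Endoderm genes had 1 call (RHOBTB3) in the authors' deposited table (adjusted p = 0.215), and the share of calls among Nodal and Activin targets missed the threshold as well (adjusted p = 0.224, Fisher exact test). The largest changes included those of LUM (4.59, SE 0.81) and COL3A1 (3.75, SE 1.93) and of genes outside the lists. ZNF275 was at 295 and 1.46 FPKM (6.91, SE 0.80), RGS4 at 77.0 and 2.12 (4.64, SE 1.13) and HGF at 29.6 and 1.79 (3.45, SE 1.05). SEMA5B was at 2.64 and 55.0 (-3.94, SE 0.69) and NRF1 at 9.69 and 140 (-3.72, SE 0.57).

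**Figure D2:**
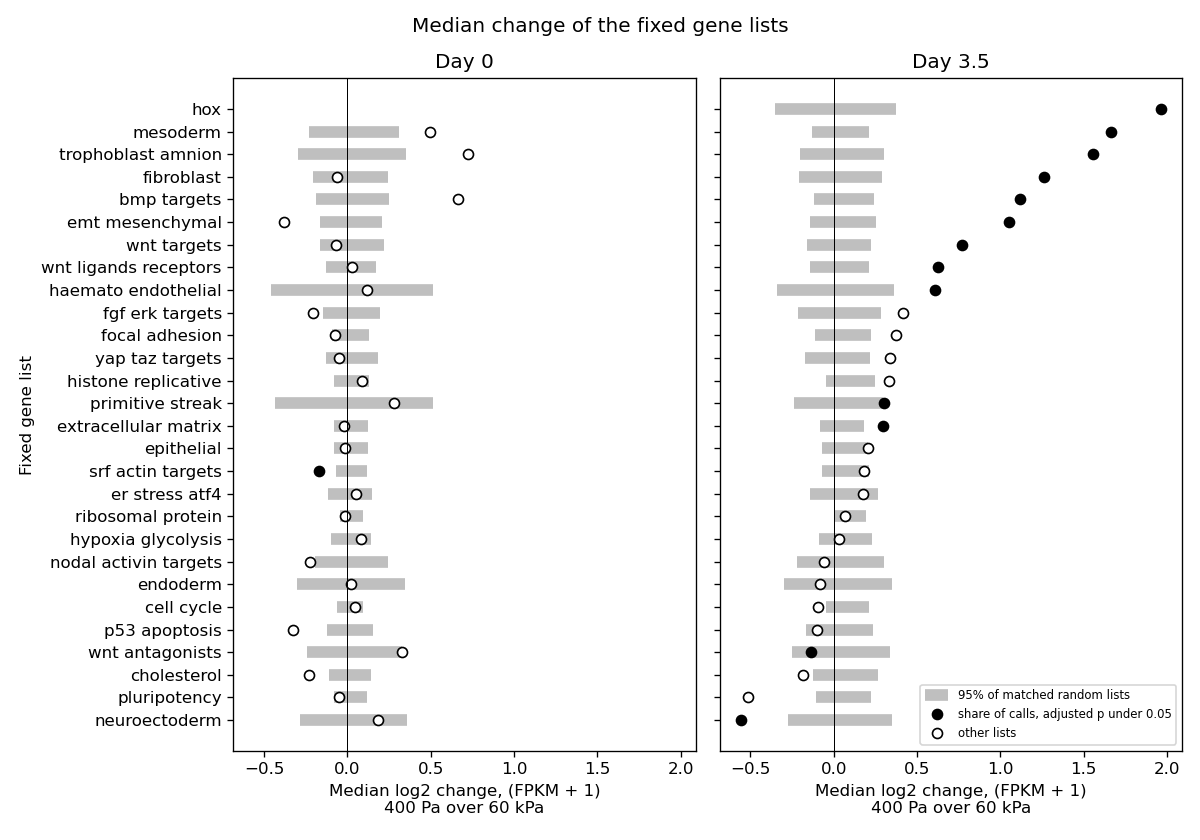
Median log2 change, 400 Pa over 60 kPa, of each fixed gene list at day 0 (left) and day 3.5 (right). Grey bars hold 95% of matched random lists, and filled points are lists whose share of calls had an adjusted p below 0.05 (Fisher exact test). At day 3.5, 13 lists are filled, and at day 0 only the serum response factor and actin list is.

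In undifferentiated cells far fewer genes were called. At day 0, ACTA1, TAGLN and VIM were called higher on the stiff gel in the authors' deposited table, and the pluripotency genes had no call. The authors' deposited table called 24 loci, 11 higher on 400 Pa and 13 higher on 60 kPa. Of the 17315 tested loci, 322 had an unadjusted p below 0.05 there. That share is under 0.05, so it is smaller than uniform p-values without any difference would give. A missing call at day 0 is therefore no evidence of equal levels. All 24 had the smallest p-value the authors' procedure gives and hence q = 0.0390 in the authors' deposited table. Without genes that hold a small RNA gene, 17 of these 24 remained, and 13 without merged and unnamed loci as well.

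Serum response factor and actin genes were the only list whose share of calls passed at day 0. In the authors' deposited table, 2 of 25 were called, both higher on 60 kPa (0 and 2 when adjusted over the list alone; Fisher exact test, adjusted p = 0.015). ACTA1, the skeletal muscle alpha-actin, was at 11.4 FPKM on 400 Pa and 32.2 on 60 kPa (change -1.43, SE 0.41). TAGLN, an actin-binding protein of smooth muscle, was at 195 and 489.6 (-1.33, SE 0.43). Of the 25 members, 20 lay below 0, with a median of -0.17 against -0.07 to 0.12 for 95% of matched lists. VIM, the intermediate filament vimentin, was called higher on 60 kPa in the authors' deposited table, at 139 and 270.2 FPKM (-0.95, SE 0.31). TFAP2A, an amnion and trophoblast factor, was called higher on 400 Pa in the authors' deposited table, at 2.41 and 0.465 FPKM, with a change of 1.22 and an SE of 1.98.

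None of the 18 pluripotency genes was called at day 0 in the authors' deposited table. Their median of -0.05 lay within 95% of matched lists (-0.08 to 0.12). BMP targets had no call of 9 in the authors' deposited table, and 4 higher on 400 Pa when adjusted over the list alone. Their median of 0.66 lay above that of 95% of matched lists (-0.19 to 0.25). ID3 was at 106 and 61.2 FPKM and ID1 at 291 and 207. The p53 list had a median of -0.33 (16 of 18 below 0), and the cholesterol list one of -0.23 (11 of 13 below 0), both without a call in the authors' deposited table. The mesenchymal transition list had a median of -0.38 and the mesoderm list one of 0.49. The amnion and trophoblast list had the highest, 0.72 (5 genes, 95% of matched lists -0.29 to 0.35). Those of FGF-ERK targets (-0.21, 13 of 15 below 0) and Nodal and Activin targets (-0.23, 7 of 9 below 0) lay below 95% of matched lists. CTGF was at 16.4 and 19.8 FPKM, and SFRP1 at 82.8 and 65.8, without a call in the authors' deposited table.

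The largest changes at day 0 lay mostly in genes that hold a small RNA gene in the reference annotation. These were IL32 (49.1 and 1.54 FPKM), MPLKIP (63.4 and 2.38), PAQR5 (63.3 and 2.47), MIR205HG (173 and 15.8) and WEE1 (531 and 79.5) on the soft side, and NIPAL2 (0.694 and 272) and CHPF2 (5.60 and 28.7) on the stiff side. SSRP1, a subunit of the histone chaperone FACT, holds none there and was at 69.3 and 642 FPKM (-3.19, SE 0.22). CBLN1 was at 8.72 and 1.53 (1.94, SE 0.81) and GCNT4 at 4.05 and 12.4 (-1.41, SE 0.52). GRM7 was at 7.28 and 0.377, with an SE of 2.66.

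The calls of both days were then compared over 15376 loci tested and expressed on both. Of 22 called at day 0 and 130 called at day 3.5 in the authors' deposited tables, 4 were shared, against 0.186 for independent lists (Fisher exact test, two-sided, p = 3.17e-05). VIM was higher on 60 kPa at day 0 and higher on 400 Pa at day 3.5, at 552 and 187 FPKM. MPLKIP, SEMA5B and GRM7 went from higher on 400 Pa to higher on 60 kPa. All 4 thus had opposite directions. A further locus, named snoU13, was called on both days in the authors' deposited tables. It is left out of this count, which takes each gene symbol once. On 400 Pa and 60 kPa it was at 1.52 and 247 FPKM at day 0, and at 361 and 0.941 at day 3.5. For GRM7 the test statistics in the authors' deposited tables were small, -1.61 and 1.21, and the difference between the days missed the threshold. MPLKIP holds a small RNA gene. Across genes, which are not independent replicates, the changes of the days had a Pearson r of 0.01 and a Spearman rho of -0.09. Of the 130 loci called at day 3.5, 44 had the same direction at day 0. Of the 34 called higher on 60 kPa, 25 were higher on 400 Pa at day 0 (median change 0.56). Of the 96 called higher on 400 Pa, 35 were higher there at day 0 as well (median change -0.10). These directions were not tested.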

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

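All tests of explanations in this part were chosen after the results had been seen. The difference between the days in the effect of stiffness was planned, and was tested from the deposited log2 ratios and their implied errors. Of 15293 loci compared, 11 had an adjusted p below 0.05, and 9 of them are named in the text. Values are the log2 ratio, 400 Pa over 60 kPa, at day 3.5 minus that at day 0. The difference was -8.75 for MPLKIP (SE 0.74), 3.28 for SSRP1 (SE 0.47), -6.25 for SEMA5B (SE 0.90) and 7.89 for ZNF275 (SE 1.20). It was 2.51 for VIM (SE 0.52), -4.28 for HESX1 (SE 0.91) and -13.72 for RP1-34H18.1 (SE 3.08). For ANXA1 and ANXA3 it was 3.13 (SE 0.69) and 3.12 (SE 0.74). The errors are a normal approximation from groups of 2 libraries.

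The largest changes at day 0 lay mostly in genes that hold a small RNA gene. Of the 20 called genes with a name of their own, 35% hold one, against a median of 15.0% and an upper bound of 30.0% in lists matched on gene span. Among the 9 with a change of at least 2 it was 7, and among the other 11 it was 0. Reads of small RNA genes inside the locus may thus contribute to the first group, which includes MPLKIP; ACTA1, TAGLN, VIM and SSRP1 hold none in the reference, which may differ from the authors' annotation. At day 3.5 the share was 14.0%, below the matched median of 19.3%. Substrate stiffness stays open for all of them.

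Of the fibroblast markers, LUM, COL3A1 and DCN were higher on 400 Pa at day 3.5. A shift of all deposited values by the loci with the highest FPKM is argued against by the median change of all expressed loci. It was 0.018, beside a median of 3.75 for these 3 genes, which were picked as called higher. The authors' normalization is not given and may itself hold that median near 0. A shift before normalization can therefore not be judged. Fibroblasts carried over from feeder culture would bring type I collagen. COL1A1 and COL1A2 together gained 2.47% of the FPKM that the 3 genes gained, but this sums opposite changes. COL1A1 gained 10.6 FPKM (7.15 to 17.8), and COL1A2 stood at 24.2 on 60 kPa and 18.2 on 400 Pa. Of the 11 markers, 8 lay above 0 and 3 below. Those below include THY1 (25.5 FPKM on 400 Pa and 26.8 on 60 kPa) and PDGFRB (4.26 and 5.65). FBLN1 hardly differed (24.9 and 24.2). MMP2 gained 31.5 FPKM, but neither MMP2 nor COL1A1 was called in the authors' deposited table. At day 0, on 400 Pa and 60 kPa, LUM was at 0.0797 and 0.0223 FPKM, DCN at 0.0977 and 0, and COL3A1 at 0.00694 and 0.0760. For these 3 genes this argues against fibroblasts already present in the day 0 libraries. Carry-over into the day 3.5 cultures alone stays open, since the days are separate libraries. A larger share of amnion- or trophoblast-like cells may contribute, since 13 members of that list outside the mesoderm list had a median of 1.5. The mesoderm list had 1.66, so such cells cannot be told apart from a general gain of mesoderm genes.

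Genes higher on 60 kPa at day 3.5 could reflect a slower exit from the day 0 state. Of 36 such genes, 63.9% (95% Wilson interval 47.6% to 77.5%, across genes) lay above 2 times their own day 0 level on 60 kPa. For the genes that rose so far this argues against a slower exit alone. The 36 genes were chosen through a high 60 kPa value at day 3.5, which favours such a rise. Of the 176 genes higher on 400 Pa, 58.5% also lay above 2 times their day 0 level on 60 kPa. The share can therefore not decide for the whole group. On 400 Pa, 19 of the 36 lay below 0.5 times their day 0 level and 7 above 2 times it. For 11 genes the 400 Pa level alone had fallen this far, without such a rise on 60 kPa. For these a slower exit, or a faster loss on the soft gel, stays open. These 11 include SFRP1, SFRP2, FZD7 and PRDM14. SFRP1 was at 65.8 FPKM on 60 kPa at day 0 and 52.5 at day 3.5, and at 82.8 and 15.4 on 400 Pa. OTX2 passed neither bound (82.2 and 152 on 60 kPa, 136 and 69.3 on 400 Pa). FRZB, HESX1, FEZF1 and LHX5 are among the 23 genes that rose this far on 60 kPa. The pluripotency list as a whole was not part of this share. Its 18 genes had a median log2 level, day 3.5 over day 0, of -1.72 on 400 Pa and -1.17 on 60 kPa. For this list too a slower exit, or a faster loss on the soft gel, stays open. The levels of the days come from separately made tables.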

How the results depend on the processing

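The alternatives that left out genes with a small RNA or unnamed and merged loci, asked for a test statistic past the two-sided normal bound at 0.05, or counted every row in the overlap were chosen after seeing the data. No paired analysis was possible because the tables hold 1 value per group and none per library. For the same reason leaving out a replicate, tests over libraries and set tests with estimated correlation were not run. At a q threshold of 0.01, the calls fell from 24 to 0 at day 0, where the smallest q is 0.0390 by construction, and from 243 to 128 at day 3.5, and the overlap fell from 4 to 0. Without genes that hold a small RNA, 17 were left at day 0, and 13 when unmatched, unnamed and merged loci were left out as well. Adjusted over the list alone, which tests fewer genes, called list genes went from 4 to 16 at day 0 and from 57 to 100 at day 3.5. With a pseudocount of 0.1, the mesoderm-list gain from day 0 to day 3.5 was 4.89 on 400 Pa and 4.29 on 60 kPa, since its genes are near 0 at day 0. The other settings gave 17 to 29 calls at day 0 and 178 to 297 at day 3.5. No named gene or list median past its threshold changed direction. The unknown depth limits low genes, and calls with an SE near the size of their change should be read with care.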

Other observations

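Families named here were chosen after their members had been seen, so no test is given. At day 3.5, 3 of 9 annexins were called higher on 400 Pa in the authors' deposited table, and 8 of the 9 lay above 0. ANXA2 was at 341 FPKM on 400 Pa and 119 on 60 kPa, ANXA3 at 82.2 and 16.6, and ANXA1 at 46.8 and 10.6. S100A10, a partner of annexin A2, was at 77.3 and 21.7, and S100A11 at 296 and 96.7, both called in the authors' deposited table. KRT7, a simple-epithelium keratin, was at 30.7 and 6.94. The T-box genes TBX4 (6.93 and 0.138) and TBX20 (3.25 and 0.341) were called higher on 400 Pa in the authors' deposited table, as was TBX3. Among 19 semaphorins, of which 8 lay above 0 (median -0.12), SEMA3D (33.0 and 10.9) and SEMA3C (10.5 and 2.63) were higher on 400 Pa, and SEMA5B higher on 60 kPa.

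Imprinted genes went both ways at day 3.5. Of 29 tested genes from a list chosen after the values were seen, 3 (H19, DIO3 and ANO1) were called higher on 400 Pa and 2 (DLK1 and MEG3) on 60 kPa in the authors' deposited table. This count leaves out merged loci, of which that of IGF2 was called higher on 400 Pa and that of MEG8 higher on 60 kPa in the authors' deposited table. H19 (chromosome 11, 2016405 to 2022700, hg19) was at 58.0 and 6.47 FPKM, and the neighbouring merged IGF2 locus at 57.0 and 4.47. ANO1 was at 2.04 and 0.179. On chromosome 14, DIO3 was at 11.2 and 1.40, whereas DLK1 in the same imprinted cluster was at 37.6 and 106 and MEG3 at 0.555 and 4.03. At day 0 DLK1 was at 1.44 and 0.561, and H19 at 0.699 and 0.378.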
